A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

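RNA from treated and untreated sho1 cells was hybridised together on two-colour arrays of yeast ORFs. Per the labels' protocols, total RNA was extracted by mechanical disruption with an RNeasy kit and labelled as first-strand cDNA with Cy3 or Cy5. The design text speaks of 2 cultures and of 4 arrays per condition with swapped fluorochromes, while 2 arrays were analysed here, one of each dye orientation. Whether each record is a single array or a mean of arrays, and whether the records share RNA extracts, is not given in the sources used here. The time of growth before the enzyme was added differs between the design text and a sample comment, so it is not stated.

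The authors deposited log2 ratios, 1 value per ORF and array. The unit was found from the values: raising 2 to each value gave a whole multiple of 0.0001, within 1% of that step, for 100% of values on both arrays, against 1.84% to 2.11% for powers of 10 or e. The column medians were -0.03 and -0.02, and the SDs over genes 0.22 and 0.20. The scanner, background correction, normalization within arrays and the rule that left spots without a value are not given in the sources used here. The direction of the ratios is not stated either. The table held 6209 rows, of which 2 control rows (3XSSC and Arabidopsis) were left out of the tests. Of 6207 ORF rows, 619 had no value on either array, 241 had one on array 1 only and 36 on array 2 only. ORF names were matched to locus tags of the R64 annotation, and 5654 matched; the other 553 kept the deposited name. No coordinates are given because no build is named for the array. No ORF name was repeated, so no spots were averaged.

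The design written before the data were examined set the orientation by the sign of the correlation between columns: below 0, one array was to be turned. The correlation was judged not to settle it, because Pearson's r was -0.012 with an interval that includes 0 while Spearman's rho was -0.26. That interval treats genes as independent replicates, which they are not, and both coefficients were below 0. Read to the letter, the rule would have turned array 1. The rule was not followed, on the ground that the shared upper ends and the cell wall stress list fixed in advance had like values in the unturned columns. This choice was made after the data were seen, and the other reading is reported beside it. Values were used as deposited, since both medians were within 0.1 of 0.

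The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided), over the 5311 ORFs with a value on both arrays. Adjusted p-values are Benjamini-Hochberg over these genes, with a threshold of 0.05. A dye term would leave no residual degrees of freedom and was not fitted. Dye effects cancel in the mean and stay in the spread only if both columns are treated over untreated; in fixed-dye columns the mean would hold the dye effect. The spread of each gene had 1 residual degree of freedom and 23.5 prior degrees of freedom shared across genes. A size rule without a test counted genes with a mean of at least 2-fold and the same sign on both arrays. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 27 lists, and set against 10000 random lists of the same size.

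The lists were fixed before the data were examined: targets of cell wall stress, wall synthesis, HOG targets, components of the HOG and cell wall integrity pathways, general stress, pheromone and filamentation targets, alpha mating type markers, ribosomal proteins, ribosome biogenesis, chaperones, the unfolded protein response, glycolysis, respiration, phosphate, amino acid, sulfur, ergosterol, histone, G1/S, G2/M, Yap1, Aft1, proteasome and mannoprotein genes. The result of 1 further list is not reported here. Genes were named by a rule also fixed then. It takes SHO1, HOG1, SLT2 and PBS2, the 12 highest and 12 lowest genes by the smaller of their absolute values on the arrays, genes past the test first, and up to 4 members per list by the same measure. Other members of a list, LRG1, and further genes in the closing section are named beyond that rule.

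On simulated data with 5311 genes, 200 of them changed, the same fit recovered 86.3% of 1.5-fold and 100% of 2-fold changes, and 7.71% of its calls were false. The simulation drew independent errors for both arrays, with variances from the prior fitted to these data and no dye effect. The real columns had a Spearman rho of -0.26, so these rates may not carry over to them. Alternatives were centring, scaling of arrays to one median absolute deviation, a turned array, single arrays, ORFs with 1 value, a filter on discordant ORFs, robust variances, other thresholds and other settings of camera. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutation tests and plots.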

Results

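Transcript ratios were measured on 2 dye-swapped DNA microarrays in a Saccharomyces cerevisiae sho1 mutant of the BY4741 background, a haploid laboratory strain. Sho1 is a plasma membrane sensor protein of one branch of the high-osmolarity glycerol (HOG) mitogen-activated protein kinase pathway. Cells were exposed for 3 hours at 24 °C to 0.8 units per ml of Zymolyase, an enzyme preparation that digests the glucan of the yeast cell wall, or were left untreated. On the array called replicate 1 the treated RNA carried Cy3, and on replicate 2 it carried Cy5. The comparison asks which transcripts respond to enzymatic wall damage in cells without Sho1. Array 1 gave a value for 5552 open reading frames (ORFs) and array 2 for 5347, and 5311 had a value on both. No spot intensities were used here, so the signal behind each ratio is unknown and the number of arrays limits the precision.

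The orientation of the deposited ratios had to be chosen before any gene could be read. Across genes the 2 columns had a Pearson r of -0.012 (95% interval -0.039 to 0.015) and a Spearman rho of -0.26. The interval treats genes as independent replicates, which they are not. Their upper ends overlapped strongly, since 13 of the 20 highest genes were shared against 0.075 by chance, and 22 of the 50 highest against 0.471. None of the 20 lowest genes was shared, and 2 of the 20 highest on array 1 were among the 20 lowest on array 2. Among the 100 highest, 36 were shared, while 18 of the 100 highest on array 1 were among the 100 lowest on array 2, against 1.88 by chance for either. Only 2 of the 100 lowest on array 1 were among the 100 highest on array 2, and 0 of the 100 lowest were shared. These counts do not settle the orientation; the columns were read as already turned the same way, for the larger overlap of the upper ends. This departs from the rule fixed before the data were examined, under which a correlation below 0 meant fixed-dye ratios and array 1 was to be turned. The shared upper ends and the cell wall stress list counted in this choice, so neither the genes high on both arrays nor the shift of that list is independent evidence of the orientation. Positive values are called higher, which likely means higher in treated cells, because the labels present both records as the same comparison of treated with non-treated cells. Turning the sign of both columns would turn every direction given here. The rule read to the letter, with array 1 turned, gave 0 genes past the test, and its counts are given beside the others.

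In the chosen orientation, the genes past the test lay on one side only and included known targets of cell wall damage. In limma's moderated test with Benjamini-Hochberg adjustment, 41 of 5311 genes passed an adjusted p of 0.05, and all 41 were higher, on both arrays. They included KDX1, a paralogue of the cell wall integrity kinase Slt2, at 2.57-fold, and CRG1, a methyltransferase gene, at 2.10-fold. The cell wall mannoprotein gene CWP1 was 1.90-fold higher. FMP27, which encodes a very large lipid transfer protein, had the highest ratio, at 4.16-fold. By size alone, 17 genes were at least 2-fold higher with the same sign on both arrays and 0 were lower, and all 17 passed the test. The same size rule gave 0 genes with array 1 turned and a median of 2, at most 7, when genes were shuffled between arrays, a comparison that restates the overlap behind the choice of orientation. Array 1 alone held 14 genes at 2-fold or more and array 2 alone 27, all of them higher. With array 1 turned, limma called 0 genes at adjusted p (lowest 0.487), with 499 at an unadjusted p under 0.05. In the main reading 191 genes had an unadjusted p under 0.05. By chance 266 were expected in either reading, more than in the main reading and fewer than with array 1 turned. The labels do not say whether the arrays came from separate cultures, so the p-values measure only the spread between 2 arrays, which may be technical.

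**Figure D1:**
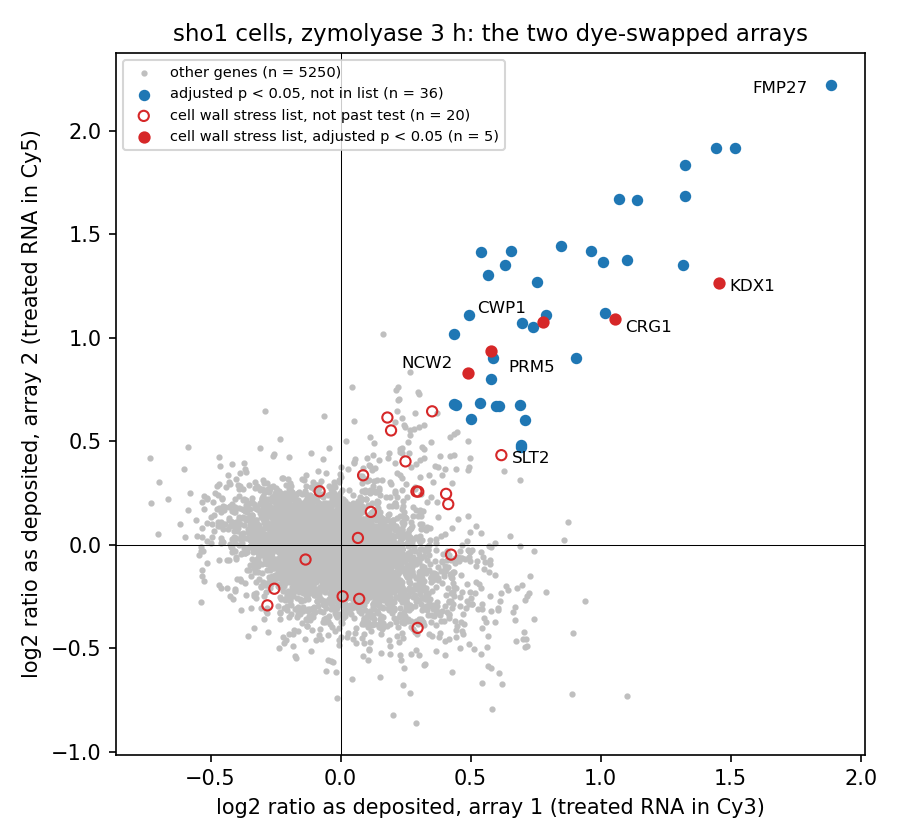
Log2 ratio of each gene on array 1 (horizontal axis) and array 2 (vertical axis), with one point per gene for the 5311 genes that had both values. The 41 genes past an adjusted p of 0.05 lie in the upper right corner, 5 of them in the cell wall stress list, while 59.2% of all genes had opposite signs on the arrays.

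The genes with the highest values on both arrays came from several functions. FMP27 had a mean log2 ratio of 2.06 ± 0.24 (SD, n = 2 arrays; limma adjusted p = 2.48e-10). PUF4, a Pumilio-family RNA-binding protein, had 1.72 ± 0.28 (n = 2; limma adjusted p = 8.39e-09). OAF1, a transcription factor activated by oleate, had 1.51 ± 0.25, and BPH1, a BEACH domain protein, had 1.40 ± 0.37. TUS1, an exchange factor for the GTPase Rho1 that acts upstream of the cell wall integrity cascade, had 1.33 ± 0.03 (n = 2; limma adjusted p = 1.76e-07). SIR4, a component of silent chromatin, had 1.37 ± 0.43. IDP2, cytosolic NADP-dependent isocitrate dehydrogenase, had 1.24 ± 0.19. YPL088W, a putative aryl alcohol dehydrogenase, had 1.07 ± 0.07. The short ORFs YLR162W and YGL088W had 1.68 ± 0.34 and 1.58 ± 0.36. In the R64 annotation YLR162W lies beside the 5S ribosomal RNA gene RDN5-6 and YGL088W overlaps the small nucleolar RNA gene SNR10. The called genes were long: 38 of the 41 had an annotated coding length, with a median of 2472 bp against 1254 bp for the 4999 tested genes with one. When genes over 2000 bp, or without a length, were left out, an alternative added after the data were seen, 16 genes passed. Of the original calls, 7 were up to 1000 bp long and 9 were over 1000 and up to 2000 bp. The filter takes the longer calls out, so its count is no test of whether the calls depend on length.

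All 27 lists were fixed in advance. At the preset correlation of 0.01 the cell wall stress list passed camera (adjusted p = 1.97e-21) and the other 26 did not. That list's like values on both arrays counted in the choice of orientation. Its camera p-values and percentile, here and below, are therefore not independent of that choice. The call is lost at an unadjusted p = 0.058 and adjusted p = 0.948 with an estimated correlation, a test that rests here on 1 residual degree of freedom. The cell wall stress list holds 26 targets of the Slt2 kinase and its transcription factor Rlm1, and 25 were measured on both arrays. Their median log2 ratio was 0.28 (0.29 on array 1 and 0.26 on array 2), with 17 members higher on both arrays, 3 lower on both and 5 of opposite sign. It lay above the medians of 10000 random lists of equal size (percentile 100), whose central 95% ran from -0.07 to 0.02. These random lists could not be matched on expression, and the medians of 8 lists in all lay outside their central 95%. The others were the glycolysis (percentile 100), pheromone (99.98) and wall synthesis (99.76) lists above it, and the general stress (0.45), chaperone (0.64), HOG target (1.18) and ergosterol (1.43) lists below it. Rank-based camera passed 3 lists, those of cell wall stress, pheromone and chaperones. With array 1 turned the list median was 0.02 and its call was lost (camera adjusted p = 0.894), while 4 other lists passed, those of ribosome biogenesis, chaperones, glycolysis and the proteasome.

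Within this list 5 genes passed the test over all genes as higher, 0 passed as lower and 20 did not pass. Adjusted over the list alone, 11 passed as higher and 0 as lower. KDX1 had a mean log2 ratio of 1.36 ± 0.13 (SD, n = 2; limma adjusted p = 1.69e-07) and CRG1 had 1.07 ± 0.02 (n = 2; limma adjusted p = 6.18e-06). CWP1 had 0.93 ± 0.21, and PRM5, a membrane protein gene induced by cell integrity signalling, had 0.76 ± 0.25. NCW2, a cell wall protein gene, had 0.66 ± 0.24 (n = 2; limma adjusted p = 0.00749). SLT2 itself had 0.53 ± 0.13 and missed the threshold (n = 2; limma adjusted p = 0.063). With each array centred on its median SLT2 passed, at a mean of 0.55 and a limma adjusted p of 0.0254. The same centring took FMP27 from a limma adjusted p of 2.48e-10 to 4.57e-40, at means of 2.06 and 2.08. Ratios that close do not account for such a fall, which points to another variance estimate in the centred fit. The pass of SLT2 is therefore not an effect of its centred ratio alone. PST1, a secreted wall protein gene, had 0.50 ± 0.21 (n = 2; limma adjusted p = 0.103), and CRH1, a chitin-glucan transglycosylase gene, had 0.37 ± 0.25. CIS3 and SRL3 had values below 0 on both arrays, with means of -0.23 and -0.29. GSC2, the stress-induced glucan synthase gene also named FKS2, was 0.30 on array 1 and -0.40 on array 2. Without the 5 called members, in an alternative added after the data were seen, the other 20 had a median of 0.20 and camera's adjusted p was 1.56e-06 at the preset correlation. That call is lost too, at an adjusted p = 0.927 with an estimated correlation.

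**Figure D2:**
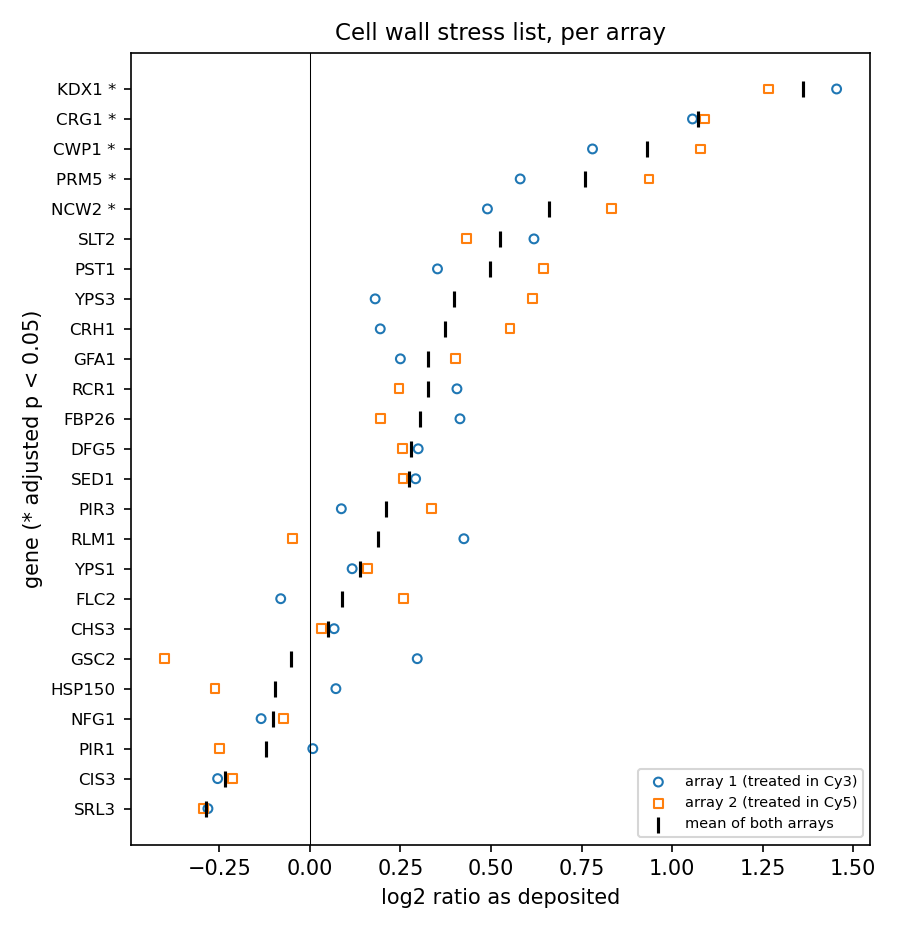
Log2 ratios of the 25 measured members of the cell wall stress list (horizontal axis), one gene per row, on array 1 (circles) and array 2 (squares), with the mean as a bar. KDX1, CRG1, CWP1, PRM5 and NCW2 (asterisks) passed the test, and 17 members were above 0 on both arrays.

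Genes of the HOG pathway and its osmotic stress targets did not pass. SHO1 had no value on either array. HOG1, the kinase of the pathway, was -0.20 on array 1 and 0.04 on array 2, and its kinase kinase PBS2 was 1.06-fold lower in the mean (limma adjusted p = 1.00). The free-text comment of one channel, the untreated RNA of array 2, names a hog1 mutant where every other label says sho1. The difference of HOG1 between arrays, 0.24, lay at percentile 82.3 of all genes. The 21 measured HOG components had a median log2 ratio of 0.02 and 0 past the test; PTP2, a phosphatase of the kinases, was 1.22-fold and MSB2, a mucin-like sensor, 1.18-fold higher without passing. The 16 measured osmotic targets had a median of -0.09 with 9 members below 0 on both arrays (camera adjusted p = 0.25). The glycerol phosphatase genes GPP1 and GPP2 had means of -0.26 and -0.18, and the glucose transporter gene HXT1 had -0.20, none of them past the test.

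Other listed genes of wall construction and integrity signalling did not pass the test over all genes. The 21 measured genes of glucan and chitin synthesis and remodelling had a median of 0.05 with 0 past the test (camera adjusted p = 0.145). CHS7, needed for export of chitin synthase III, was 1.21-fold and FKS1, the main glucan synthase, 1.18-fold higher without passing. The 19 measured components of the cell wall integrity pathway had a median of 0.01, 14 had opposite signs on the arrays, and 0 passed over all genes against 1 adjusted over the list alone, SLT2. RHO1, its GTPase, was 1.07-fold higher. LRG1 is a GTPase-activating protein for Rho1 outside the fixed lists and was chosen after its value was seen. It had a mean log2 ratio of 0.90 ± 0.22 (n = 2, limma adjusted p = 0.000135).

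General stress genes showed no member past the test. The 23 measured targets of Msn2 and Msn4 had a median log2 ratio of -0.09, and 11 were below 0 on both arrays (camera adjusted p = 0.145). YGP1, a secreted glycoprotein gene, had a mean of -0.24, and HSP12, a heat shock protein gene, had 0.13. The 22 heat shock chaperone genes had a median of -0.09, with 0.00042 on array 1 and -0.17 on array 2 (camera adjusted p = 0.145), and passed camera with array 1 turned. The 13 Yap1 oxidative stress targets had a median of -0.09, the 14 unfolded protein response genes 0.004 and the 30 proteasome genes -0.02, each with 0 past the test. The proteasome list passed camera with array 1 turned.

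Mating and filamentation genes, which share kinases with the Sho1 branch, also had no member past the test. The 16 measured Ste12 pheromone targets had a median of 0.07 (camera adjusted p = 0.145), and FUS1, a cell fusion gene, had a mean of 0.06. The 5 measured Tec1 targets had a median of -0.02. Markers of the other mating type, alpha, were measured by 2 spots with a median of -0.08. SAG1, the alpha-agglutinin gene, was 1.08-fold lower in the mean.

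Growth and metabolism lists had 1 member past the test among them. That gene was UTP20, an rRNA processing factor, with a mean of 0.98 ± 0.62 (n = 2; limma adjusted p = 0.000369), 0.54 on array 1 and 1.42 on array 2. The other 61 ribosome biogenesis genes did not pass, and the list's median was -0.05. The 129 measured cytosolic ribosomal protein genes had a median of -0.04 with 46 below 0 and 17 above 0 on both arrays (camera adjusted p = 0.366). Members of that list share sequence with their paralogues, so their spots cannot be told apart fully. Glycolysis and fermentation genes had a median of 0.11 but a mean of -0.003, with 0.24 on array 1 and -0.02 on array 2, and 12 of the 16 had opposite signs. The glycolysis and ribosome biogenesis lists did not pass camera as deposited but did with array 1 turned. Respiration and TCA cycle genes had a median of -0.02, Pho4 targets -0.01, Gcn4 targets -0.06, Met4 targets -0.01, ergosterol genes -0.08 and Aft1 iron regulon genes -0.08, with 0 past the test in each. Histone genes had a median of -0.09, G1/S targets -0.04, G2/M targets -0.02 and the anaerobic and cold mannoproteins -0.09, again with 0 past the test. Camera's direction differed in sign from the median or the mean in 6 of the 27 lists, those for filamentation, the unfolded protein response, glycolysis, respiration, phosphate and G2/M.

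No gene passed limma's test on the lower side, where 59 genes had an unadjusted p under 0.05. The lowest adjusted p among genes with a mean below 0 was 0.361. The genes with the most negative values on both arrays were PRY1, a sterol-binding secreted protein gene, at -0.36 and -0.44, followed by DCG1, LAM5 and YLR269C. DAL5, an allantoate transporter gene, had a mean of -0.41 ± 0.18 (n = 2; limma adjusted p = 0.361). ATH1, the acid trehalase gene, had -0.35 ± 0.10, and VPS13, a lipid transfer protein gene, had -0.33 ± 0.05. The remaining genes of the 12 lowest, TVS1, PRP24, ISC1, YAR068W and SRL3, had means between -0.31 and -0.29.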

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

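The length filter and the removal of called members, with either correlation, were chosen after the data were seen; the other alternatives were planned. The largest dependence was on the orientation of the columns. With array 1 turned, 0 genes passed (499 at an unadjusted p under 0.05), 0 were 2-fold by size, the cell wall stress list had a median of 0.016 (adjusted p = 0.894), KDX1 went to -0.094, and 4 other lists passed: ribosome biogenesis, heat shock chaperones, glycolysis and the proteasome. That reading is what the rule fixed in advance gives when read to the letter, and the cause of the difference was not tested. Under the other planned fits, the count past the test ran from 25 (tested against 1.2-fold) to 54 (centred arrays), always with 0 lower, and all 41 calls were kept under centring and under scaling. By size, 38 genes were at least 1.5-fold, against 11 with array 1 turned, and single arrays gave 14 to 27 genes at 2-fold. Lists past the threshold numbered 1 with the preset correlation, 3 with rank-based camera (cell wall stress, pheromone and chaperones) and 0 with an estimated correlation. With the estimated correlation the cell wall stress list, median 0.278, had a camera adjusted p = 0.948. Without its called members, median 0.20, that adjusted p was 0.927. At the preset correlation the list's camera adjusted p ran down to 3.92e-36, reached with genes over 2000 bp or without a length left out. Without genes over 2000 bp, 16 genes passed, 7 were 2-fold and 2 lists passed, cell wall stress and general stress. Fewer genes were tested, 3840, and the longer calls were among those taken out, so the 16 is no test of length. The filter on arrays that differ by over 2 removed no gene and tests nothing. The median of repeated spots was not run, since no ORF is repeated, and single arrays allow no gene test. Both RNAs of each array enter one ratio, so the test against 0 already uses their pairing on the array. The 2 arrays form a single group, so no further pairing was possible. With 2 arrays and no intensities, dim spots could not be told from bright ones.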

Other observations

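Of the tests below, those of the ORF-name order and of HOG1 were set before their result was seen, and the others after it. Retrotransposon spots, listed after their values were seen, formed a group that the lists did not hold. All 11 spots of Ty TYA ORFs, which encode the Gag capsid protein, were higher on both arrays, with a median log2 ratio of 0.45 on array 1 and 0.47 on array 2, and 3 of them passed limma's test (YBL101W-A, YBR012W-A and YFL-TYA). The 14 TYB spots, for the polymerase part of the same elements, were higher on array 1 (median 0.51, 14 of 14 above 0) but mostly lower on array 2 (median -0.14, 13 of 14 below 0), and 0 passed. The means averaged 0.47 ± 0.10 (SD over 11 TYA spots) and 0.14 ± 0.15 (SD over 14 TYB spots). With array 1 turned, the 11 TYA spots would have opposite signs and 13 of the 14 TYB spots would be lower on both arrays. Copies of Ty elements are near-identical and cross-hybridise, so these spots are not independent measurements, and the difference between TYA and TYB was not tested.

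Besides KDX1, CRG1, CWP1, PRM5, NCW2 and UTP20, 35 of the 41 called genes were in no list. They include the regulators of Rho1 TUS1 (1.33) and LRG1 (0.90), the GATA factor GAT1 (0.61), the mannosyltransferase PMT6 (0.94), the aromatic amino acid enzyme ARO1 (1.15), the exosome helicase SKI2 (1.04), the replication fork protein TOF1 (1.19), the deacetylase subunit SIN3 (0.74) and the histone chaperone subunit SPT16 (0.66), as mean log2 ratios; those other than TUS1 were chosen after their values were seen.

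The 41 genes higher on both arrays were long: their median coding length exceeded that of every one of 100000 random draws (one-sided permutation p = 1e-05, the smallest these draws can give; highest draw 2259 bp). Called genes made up 2.96% of the 439 tested genes over 3000 bp and 0.38% of the 1841 up to 1000 bp, whereas the 5 called genes of the cell wall stress list had a median of 876 bp. Dye bias with fixed-dye columns stays open: the cell wall stress list had a median half-difference (array 2 minus array 1, divided by 2) of 0.0165, inside the random range, but its like values on both arrays counted in the choice of orientation. A shift of all long genes is argued against by the 733 genes at least as long as the median called gene, whose median log2 ratio was -0.00735 (quartiles -0.08 and 0.07). A shared source of neighbouring ORFs stays open, since the median distance in name order was 87.5 ranks for called and 89.5 for random genes (permutation p = 0.454) and the array layout was not used here; a response to the enzyme also stays open.

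The comment that names a hog1 mutant for the untreated RNA of array 2 may be a slip in the text. Were that RNA from a hog1 deletion, HOG1 would be far higher in the treated RNA of that array, if its spot gave signal above background. That is unknown without intensities. The log2 ratio of HOG1 on array 2 was 0.0386, within the central 95% of genes. By the rule set before this value was seen, it counted against RNA from a hog1 mutant. SHO1 had no value on either array, so it gives no check of the deletion. Of the genes that BY4741 carries in mutant form, MET17 and URA3 had no value, while HIS3 was -0.24 and 0.03 and LEU2 was -0.30 and 0.06. How much of each ORF the strain lacks was not checked here. HOG1 had similar values, -0.20 and 0.04. If the strain makes no RNA that the HIS3 or LEU2 spot can bind, a ratio near 0 does not show that HOG1 RNA was present. The outcome of the preset rule was set aside for this reason, after the values were seen. The check is taken as unable to tell whether the untreated RNA of array 2 came from a hog1 mutant.

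On the arrays, 3146 of 5311 genes had values of opposite sign. Independent spot noise would leave no correlation, and the Spearman rho of -0.2625 across genes, which are not independent replicates (permutation p = 0.0001, the smallest these permutations can give), argues against it as the whole cause. If the columns are fixed-dye ratios, a response to the enzyme would itself give opposite signs, and that reading stays open. With array 1 turned, 4 lists passed camera, those of ribosome biogenesis, chaperones, glycolysis and the proteasome. In that reading 0 genes passed limma's test and the cell wall stress list did not pass camera. A reproducible dye effect tied to the sequence of a spot is another candidate explanation. Half-differences correlated across 50 ribosomal protein paralogue pairs (Pearson r = 0.4107, Spearman rho = 0.08, permutation p = 0.0123), but r was -0.003 without the 2 pairs farthest from the median, so it rests on those pairs, and the means correlated across the same pairs as well (r = 0.404, rho = 0.443, permutation p = 0.00395), so a correlation is not particular to a dye effect. RPS30A and RPS30B had half-differences of -0.53 and -0.69.

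ECM11 was the only ORF measured on a single array with a ratio of at least 2-fold, at 1.24 on array 1. The control spots 3XSSC and Arabidopsis had ratios of -0.01 and 0.06 on array 1 and 0.16 and 0.31 on array 2.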
